A study of Mus musculus with 14 samples.

How the data were processed

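Liver RNA of mice was measured on 1-colour expression arrays with a biotin label. The labels give 7 groups of 2 arrays, normal liver and liver 4, 8, 12, 36, 48 and 72 h after partial hepatectomy (PHx). The design text says that livers of 4 to 6 mice were pooled for each RNA extraction, and that the authors used GeneSpring 7.2 to select genes that differed 2-fold from normal liver. The software that made the values is not given in the sources used here. The deposited values are of intensity on a linear scale, 1 per probe set, with 0 negative values and 1 zero. After the lowest and highest 2 percent were left out, the mean of every array lay between 500.2 and 500.3, so the arrays had been scaled to each other.

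Of 22690 probe sets, 64 are controls, which were left out of the tests. Gene names came from the annotation of the array; 20380 of the other 22626 probe sets have 1 symbol, 691 several and 1555 none. The symbols of 20351 were matched by gene identifier to the gene table of assembly GRCm38.p6, and 0 changed. Intensities were put on the log2 scale after adding 57, the 25th percentile, with the deposited scaling kept. Probe sets with a mean intensity at or above the 40th percentile, 128.8, were tested. Background on an array was the 95th percentile of 27 bacterial control probe sets (43.56 to 138.3). Where no array of one side of a comparison was above it, the fold is a lower bound against the background and is written as at least that fold. No size is given where 1 array was above it but the mean of the group was below the background of both.

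A linear model with 7 groups was fitted to all 14 arrays in limma 3.58.1 (R 4.3.3), with moderated variances (7 residual and 5.08 prior degrees of freedom). It gave 9 contrasts, each time against normal liver, the early times (4, 8 and 12 h) against the late times, 12 against 4 h and 72 against 36 h, and a moderated F test over the 6 times. P-values were adjusted by Benjamini-Hochberg within each contrast, at a threshold of 0.05. Camera in limma tested 32 gene lists with at least 5 measured members in 9 contrasts (288 tests, adjusted together), with the preset correlation of 0.01 and with an estimated one. The lists were of immediate-early genes, acute phase, cytokines and NF-kB targets, interferon response, growth factors and receptors, glucocorticoid and fasting response, DNA replication, mitosis, p53 targets, ribosome biogenesis, proteasome, ER stress, heat shock, NRF2 response, circadian clock and male-biased genes. Others were of cholesterol, fatty acid and bile acid synthesis, fatty acid oxidation, cytochrome P450, gluconeogenesis, urea cycle and amino acid catabolism, and coagulation. Marker lists were of Kupffer cells, neutrophils, lymphocytes, endothelium, stellate cells, cholangiocytes, erythroid cells, and pancreas and adipose tissue. These lists, 25 landmark genes, the tests, the rule for naming genes and the alternatives below, unless said otherwise, were fixed before the data were examined. Of the landmark genes 22 were tested, and the others are not reported here. The added lists of pancreatic acinar, pancreatic islet and skeletal muscle transcripts were written after the data were seen.

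Named genes were the 10 largest rises and falls of each contrast among called probe sets with 1 symbol that are the brightest of their gene. Their arrays had not to overlap between the sides, and their higher side had to reach the median of probe set means, 402.8. Up to 4 called members of each list and the landmark genes were added. The rule was applied again without genes of the 3 added lists, a choice made after the data were seen.

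The alternatives were quantile normalization, pseudocounts of 14.25 and 228, no filter, a filter at the 60th percentile, an intensity trend in the prior variance, array weights, the replicate number as a block, 1 probe set per gene, the mean of a gene's probe sets, each array left out in turn, only the 4 arrays of a comparison, 2-fold without a test, and for early against late times a fit of 2 groups. Added after the data were seen were the processing group as a block, the fit without its 4 arrays, a comparison within these 4 and counts without the 3 added lists. The processing group is the 4 arrays whose pyruvate carboxylase 5′ signal is under 0.2 of the 3′ signal.

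The procedure was tested on simulated data with this design. It recovered 14% of 100 probe sets changed by 1 in log2 and 88% of 100 changed by 2, with 3 false calls among 13576. A mitosis list raised by 0.8 at 36 h was called in 3 of 3 contrasts that contain it, with 0 calls in the 285 other list tests. The seed was 1.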

Results

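The series holds expression profiles of mouse liver before and after partial hepatectomy (PHx), the surgical removal of part of the liver, which then grows back. Total RNA was measured on 14 arrays, 2 for normal liver and 2 each at 4, 8, 12, 36, 48 and 72 h after PHx. The table has 22690 probe sets, of which 13576, for 8453 genes, were bright enough to be tested. The median intensity of an array lay between 127.8 and 233.1, and the number of arrays limits the precision. The labels do not say whether the 2 arrays of a group came from separate pools of animals, so p-values measure only the spread between these samples, which may be technical. Changes are differences of log2 intensity with the standard error (SE) of the limma fit, for 2 arrays against 2 unless stated. For gene lists, the adjusted p of camera in limma is given with its preset correlation between genes and then with an estimated one, marked estimated. Counts of list members are adjusted over all probe sets, and then adjusted over the list alone.

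Replicate arrays correlated across probe sets at 0.952 in normal liver, 0.970 at 4 h, 0.963 at 8 h, 0.910 at 12 h, 0.948 at 36 h, 0.942 at 48 h and 0.957 at 72 h, and arrays of different groups at 0.824 to 0.962. These are correlations across genes, which are not independent replicates. Replicate 2 of the 8, 12, 36 and 72 h groups stood apart in the control probe sets. In these 4 arrays the 5′ signal of the pyruvate carboxylase control was 0.091 to 0.137 of its 3′ signal, against 0.305 to 0.584 in the other 10 arrays. Values "with the block" come from a fit that holds this split as a term. Values "without the 4 arrays" leave 1 array at 8, 12, 36 and 72 h; both were chosen after the data were seen. A pair in square brackets after a list median gives that median in these 2 ways. The 4 and 48 h groups hold no such array.

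Over the whole course 1783 probe sets (13.1% of those tested), for 1187 genes, changed at some time by the moderated F test of limma. The count was 1739 with the block, 523 without the 4 arrays, 1717 without genes of the pancreas and muscle lists, and 1187 without replicate 2 of the 4 h group. Most calls fell at 8 and 12 h, with the highest count at 12 h. That peak depends on the fit: with array weights 1215 passed at 8 h and 584 at 12 h, and with only the 4 arrays compared 922 and 323, beside 318 at 4 h. Quantile normalization moved the median of all probe sets at 48 h from 0.12 to 0, and at the other times by 0.1 or less.

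**Figure D1:**
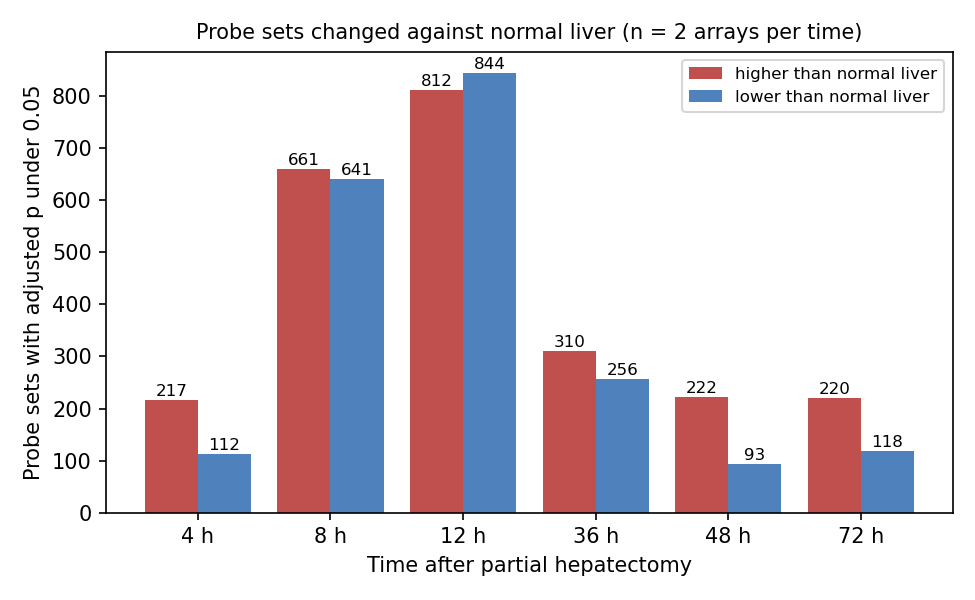
Number of probe sets (vertical axis) that passed the limma test at each time after partial hepatectomy (horizontal axis), with rises and falls as separate bars, 2 arrays against 2 of normal liver. The counts of this fit peak at 12 h, with 812 rises and 844 falls, and their total is lowest at 48 h, with 222 and 93.

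At 4 h after the operation Saa1 and Saa2, serum amyloid proteins that the liver secretes in inflammation, rose by 5.08 (SE 0.29, adjusted p = 9.33e-06) and 5.20 (SE 0.32, adjusted p = 9.33e-06) on the log2 scale. The mean intensity of Saa1 went from 1053 ± 17.1 (SD, n = 2) in normal liver to 37700 ± 6740 (SD, n = 2). Gadd45b, a stress-induced regulator of MAP kinase signalling, was at least 53.8-fold higher (adjusted p = 0.000794). Neat1, a long noncoding RNA of nuclear paraspeckles, fell by 3.69 on the log2 scale (SE 0.54, adjusted p = 0.00362).

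Other genes that rose at 4 h code for Lcn2, an iron-sequestering protein of the acute phase (4.77, SE 0.49), Pdk4, a kinase that restrains glucose oxidation (4.91, SE 0.57), and the metallothioneins Mt1 (3.50, SE 0.26) and Mt2 (4.00, SE 0.29). Cxcl1, a neutrophil-attracting chemokine, rose by 3.75 (SE 0.41), and Socs3, a feedback inhibitor of cytokine signalling, by 3.54 (SE 0.33). Cdkn1a, the cell cycle inhibitor p21, rose by 3.03 (SE 0.37, adjusted p = 0.000952). Among the falls were Hhex, a liver transcription factor (-2.35, SE 0.24), and Ppp1r3c, which targets a phosphatase to glycogen (-2.49, SE 0.34). Angptl8, an insulin-induced secreted protein, fell by 2.22 (SE 0.29), and Mid1ip1, an activator of fatty acid synthesis, fell by 2.28 (SE 0.21). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell by 2.04 (SE 0.30, adjusted p = 0.00382), and its other probe set fell without passing. Igfbp1 and Jun did not pass, at 1.99 (SE 0.48, adjusted p = 0.0524) and 1.25 (SE 0.31, adjusted p = 0.0581). Jun rose no more at 12 h, where it passed under a looser adjustment. Myc was at 0.34 (SE 0.39) and Srebf1, a regulator of lipid synthesis, at -1.26 (SE 0.31, adjusted p = 0.0554). The landmark genes Ccnd1, Ccna2, Cdk1, Mki67, Mcm5, Pcna, Rrm2, Foxm1, Alb, Afp, Hgf, Cyp2e1 and Dbp did not pass at 4 h either, with log2 changes from -0.24 (Pcna) to 1.03 (Ccnd1) for those above background; Cdk1 and Mki67 were not on one side.

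Of 20 immediate-early genes 5 rose and 15 did not pass (11 rose over the list alone), with a median of 1.07 and, in camera, adjusted p = 2.95e-11, or 0.188 estimated. Junb, a component of the transcription factor AP-1, rose by 2.33 (SE 0.37) and Rhob, a small GTPase, by 1.60 (SE 0.25). The acute-phase list had 9 of 25 members up, 16 not past the test and 11 up over the list alone (median 0.48, adjusted p = 5.05e-13, or 0.0292 estimated). Il1r1, the interleukin 1 receptor, rose by 2.65 (SE 0.24). In the glucocorticoid and fasting list 5 of 17 genes rose, 2 fell and 10 did not pass (11 and 3 over the list alone), with a median of 0.89 (adjusted p = 8.10e-06, or 0.0308 estimated). Lpin1, a phosphatase of lipid synthesis, rose by 1.64 (SE 0.30), while Klf15, a transcription factor of amino acid breakdown, fell by 1.25 (SE 0.25). Of 10 cytokine and NF-kB genes 1, Cxcl1, rose and 9 did not pass (7 rose over the list alone), with a median of 0.99 (adjusted p = 3.56e-07, or 0.137 estimated).

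Other upward shifts at 4 h passed camera, none with an estimated correlation. The p53 target list had 2 of 13 up and 11 not past the test (median 0.40, adjusted p = 0.0149, or 0.183 estimated). Of 14 NRF2 genes 3 rose and 11 did not pass (0.26, adjusted p = 0.0337, or 0.341 estimated), with Hmox1, which breaks down haem, at 2.68 (SE 0.63, adjusted p = 0.0466, and not past the test with the block). In the ribosome biogenesis list 0 of 23 genes rose by limma, against 3 over the list alone (0.21, adjusted p = 0.0224, or 0.228 estimated). The circadian list had 1 of 14 up, and 6 up and 1 down over the list alone (0.79, adjusted p = 0.00523, or 0.074 estimated). Neutrophil markers had 1 of 9 up and 8 not past the test (0.61, adjusted p = 0.00039, or 0.155 estimated), led by S100a8, a calcium-binding protein of these cells (adjusted p = 0.00954). Kupffer cell and macrophage markers had 1 of 18 up, Cd14 (2.60, SE 0.54), a median of 0.24 and adjusted p = 0.0344, or 0.299 estimated. Stellate cell and fibroblast markers had 3 of 18 up, among them Timp1, an inhibitor of matrix proteases (1.25, SE 0.22), and Col4a1 (1.43, SE 0.24), with a median of 0.15 and adjusted p = 0.0262, or 0.153 estimated. Cholangiocyte and progenitor markers had 0 of 7 up by limma and 3 over the list alone (0.45, adjusted p = 0.0179, or 0.395 estimated).

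Transcripts of skeletal muscle and exocrine pancreas were also high at 4 h. Acta1, skeletal actin, was at least 86.2-fold higher (adjusted p = 0.000668) and Mb, myoglobin, at least 41.6-fold (adjusted p = 0.000288). Of 20 muscle transcripts, a list written after the data were seen, 16 rose and 4 did not pass (17 rose over the list alone), with a median of 3.10. Of 32 pancreatic acinar transcripts, likewise written afterwards, 11 rose and 21 did not pass (22 rose over the list alone), with a median of 2.58. Clps, pancreatic colipase, rose by 4.29 (SE 0.46, adjusted p = 0.000424). The pancreas and adipose marker list fixed before had 5 of 9 up and 9 over the list alone (median 4.29, adjusted p = 2.95e-11, or 0.107 estimated). The median acinar intensity was 792 and 715 in the 4 h arrays against 123.7 and 42.63 in normal liver, and the muscle median was 879.1 and 848.8 against 102.3 and 29.19. Cela3b, Cpa1, Cpb1 and Ctrb1, all pancreatic digestive enzymes, passed at 4 h (adjusted p = 0.0403, 0.0435, 0.049 and 0.0337) but not under quantile normalization, among other settings.

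In all, limma called 217 rises and 112 falls at 4 h among 13576 probe sets (2.42%), for 145 and 75 genes, of which 208 and 110 were at least 2-fold. The total of 329 was 394 with the block, 317 without the 4 arrays and 297 without genes of the pancreas and muscle lists. It was 93 without replicate 2 of normal liver, 80 and 84 without replicate 1 or 2 of the 4 h group, and 554 without either replicate of the 12 h group. Of 47 named genes that passed, 46 also passed with the block, and 22 without replicate 1 of the 4 h group. The 13 lists called higher were 7 without replicate 1 of normal liver.

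At 8 h Hsd3b5, a steroid dehydrogenase of male mouse liver, was at least 44.4-fold lower (adjusted p = 1.49e-05), from a mean intensity of 3773 ± 1020 (SD, n = 2) in normal liver to 13.05 ± 3.04 (SD, n = 2). Keg1, an acyltransferase-like gene of liver and kidney, fell by 3.79 (SE 0.24, adjusted p = 6.01e-06), and Coq8a, a kinase-like protein of coenzyme Q synthesis, fell by 3.31 (SE 0.34, adjusted p = 0.000154). G6pc, the last enzyme of glucose release, fell by 3.22 (SE 0.45, adjusted p = 0.00116). Lcn2 rose by 6.33 (SE 0.49, adjusted p = 1.97e-05), and Saa1 by 5.08 (SE 0.29, adjusted p = 5.75e-06).

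Further rises at 8 h were those of Cidec, a lipid droplet protein (at least 40.1-fold), and Nupr1, a stress-induced transcription regulator (at least 32.9-fold). Tnfrsf12a, the receptor of the cytokine TWEAK, rose by 4.17 (SE 0.72) and Il1r1 by 3.86 (SE 0.24). Mt1 (3.39, SE 0.26), Mt2 (4.06, SE 0.29), Cxcl1 (3.65, SE 0.41), Socs3 (3.27, SE 0.33) and Cdkn1a (2.95, SE 0.37) passed too. Dnajb9, a chaperone of the endoplasmic reticulum, rose by 2.18 (SE 0.28). Among the falls, Pnkd was at -3.20 (SE 0.25), while its other probe set fell without passing, and Hsd3b2, a steroid dehydrogenase, was at least 7.08-fold lower. Igfals, a carrier of insulin-like growth factors, fell by 2.79 (SE 0.34). Cyp7a1 fell by 2.36 (SE 0.30, adjusted p = 0.000575) and Srebf1 fell by 2.09 (SE 0.31, adjusted p = 0.0015). Cdk1, not above background at 8 h, was at least 1.14-fold lower (adjusted p = 0.0322, and not past the test with the block). Myc, Jun, Ccnd1, Ccna2, Mki67, Mcm5, Pcna, Rrm2, Foxm1, Igfbp1, Alb, Afp, Hgf, Cyp2e1 and Dbp did not pass, with log2 changes from -0.46 (Myc) to 1.29 (Foxm1) for those above background.

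Several lists of liver metabolism lay lower at 8 h, most with the preset correlation only. Of 19 cholesterol synthesis genes 9 fell and 10 did not pass (11 fell over the list alone), with a median of -0.65 [-0.67, -0.73] and adjusted p = 1.99e-09, or 0.00715 estimated. Mvk, mevalonate kinase, was at least 7.83-fold lower, and Fdft1, squalene synthase, fell by 1.85 (SE 0.23). Bile acid genes had 7 of 20 down and 12 over the list alone, with a median of -0.83 [-0.71, -0.68] (adjusted p = 1.71e-07, or 0.075 estimated). Nr0b2, the bile acid sensor's target SHP, fell by 2.03 (SE 0.34). Fatty acid synthesis had 5 of 17 down and 7 over the list alone, with a median of -0.74 [-0.60, -0.86] (adjusted p = 0.000408, or 0.074 estimated). Mlxipl, a glucose-responsive transcription factor, fell by 2.03 (SE 0.33). Coagulation and complement genes had 8 of 25 down and 14 over the list alone, with a median of -0.66 [-0.73, -0.75] (adjusted p = 6.48e-09, or 0.18 estimated). Serpind1, heparin cofactor II, fell by 1.68 (SE 0.32).

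Cytochrome P450 genes had 6 of 31 down and 1 up at 8 h (10 down over the list alone), urea cycle and amino acid genes 4 of 25 (5), gluconeogenesis genes 3 of 13 (3), male-biased liver genes 2 of 13 (5) and interferon response genes 2 of 13 (7). Their medians lay between -0.37 (urea cycle) and -0.92 (male-biased), from -0.28 to -0.73 with the block and from -0.30 to -0.90 without the 4 arrays. The adjusted p went from 0.000133 to 0.00279, and from 0.0524 to 0.358 with an estimated correlation. Prodh, proline dehydrogenase, fell by 1.46 (SE 0.25), and Ifi47, an interferon-induced GTPase, fell by 1.04 (SE 0.28). None of the 21 fatty acid oxidation genes passed by limma (3456 of all probe sets had an unadjusted p under 0.05), with a median of -0.12 (adjusted p = 0.297).

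Ribosome biogenesis had 11 of 23 genes up at 8 h and 12 not past the test (12 up over the list alone). Its median was 0.84 [0.89, 0.94] (adjusted p = 5.97e-07, or 0.0397 estimated). Nop58, a core protein of small nucleolar particles, rose by 2.13 (SE 0.30), and Gnl3, nucleostemin, by 1.66 (SE 0.22). The acute-phase list had 11 of 25 up and 12 over the list alone (median 0.64 [0.66, 0.62], adjusted p = 1.96e-07, or 0.0746 estimated). In the glucocorticoid and fasting list 7 of 17 rose and 2 fell, and 8 and 2 over the list alone (median 0.59 [0.63, 0.86], adjusted p = 0.00142, or 0.0779 estimated). Cytokine genes had 1 of 10 up (median 0.70 [0.57, 0.67], adjusted p = 0.00554, or 0.346 estimated). Neutrophil markers had 2 of 9 up, S100a8 (adjusted p = 0.00124) and S100a9 (2.54, SE 0.56), with a median of 0.83 [0.76, 0.79] (adjusted p = 0.00196, or 0.191 estimated). Cholangiocyte and progenitor markers had 3 of 7 up (median 1.0 [0.91, 0.99], adjusted p = 0.00667, or 0.353 estimated). They are the keratins Krt8 (1.56, SE 0.40, and not past the test with the block) and Krt18 (1.42, SE 0.30) and the surface protein Cd24a (1.0, SE 0.24).

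Pancreatic acinar transcripts peaked at 8 h, in both arrays. Of 32, 29 rose and 3 did not pass (30 rose over the list alone), with a median of 6.04. Cela3b was at least 543-fold higher (adjusted p = 0.00196) and Cpa1 at least 421-fold (adjusted p = 0.0016). The median acinar intensity was 9633 and 8326 in the 8 h arrays. The fixed list of pancreas and adipose markers had 9 of 9 up (median 7.13 [6.96, 7.15], adjusted p = 5.24e-11, or 0.109 estimated). Muscle transcripts rose in 13 of 20 cases (18 over the list alone, median 2.05), with intensities of 488.8 and 517.5. Of 15 pancreatic islet transcripts 2 were tested, and Ins2, insulin, was at least 11.1-fold higher (adjusted p = 0.00219).

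**Figure D2:**
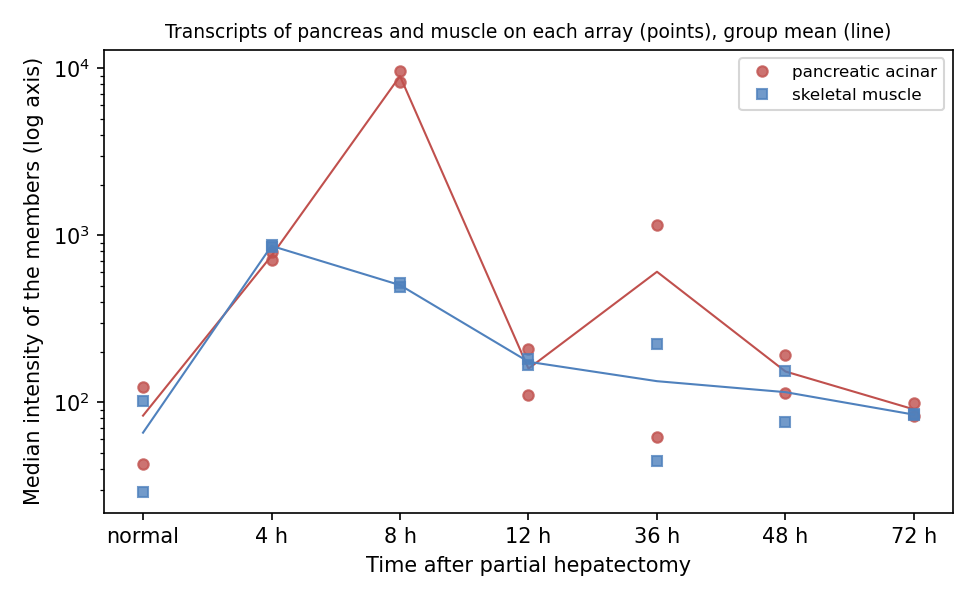
Median intensity on a log axis of the pancreatic acinar and skeletal muscle transcripts (vertical axis) on each array (points) by group (horizontal axis). Acinar transcripts peak at 8 h, at 9633 and 8326, and muscle transcripts at 4 h, at 879.1 and 848.8; the 36 h arrays differ from each other, at 61.59 and 1148 for the acinar list.

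At 8 h limma called 661 rises and 641 falls (9.59% of probe sets), for 423 and 441 genes, of which 543 and 490 were at least 2-fold. The total of 1302 was 1198 with the block, 1239 without genes of the pancreas and muscle lists and 364 without the 4 arrays, which leaves 1 array of this time. It was 458 without replicate 2 of normal liver, and 534 and 454 without replicate 1 or 2 of the 8 h group. Of 96 named genes that passed, 88 did so with the block and 61 without the 4 arrays.

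At 12 h Lcn2 rose by 5.90 (SE 0.49, adjusted p = 5.04e-05), Saa2 by 5.34 (SE 0.32, adjusted p = 4.50e-06) and Tnfrsf12a by 4.82 (SE 0.72, adjusted p = 0.00151). Hsd3b5 was at least 31-fold lower (adjusted p = 3.17e-05), and Keg1 fell by 4.24 (SE 0.24, adjusted p = 4.50e-06). The mean intensity of Lcn2 was 27800 ± 25300 (SD, n = 2).

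Cidec was at least 33.9-fold higher at 12 h, and Sult1e1, which inactivates oestrogens, at least 16.7-fold. Rab30, a small GTPase of the Golgi, rose by 4.23 (SE 0.56), Pdk4 by 3.91 (SE 0.57) and Il1r1 by 3.80 (SE 0.24). Saa1 (5.09, SE 0.29), Mt1 (3.47, SE 0.26), Socs3 (3.33, SE 0.33), Cdkn1a (3.40, SE 0.37), Jun (1.22, SE 0.31) and Dbp, a clock-controlled transcription factor (0.98, SE 0.25), also passed. Falls were those of Ddc, aromatic amino acid decarboxylase (-2.99, SE 0.33), Hal, histidine ammonia-lyase (-3.00, SE 0.31), G6pc (-2.93, SE 0.45) and Ppp1r3c (-2.98, SE 0.34). Acacb, acetyl-CoA carboxylase of mitochondria, was at least 9.38-fold lower. Cyp7a1 fell by 2.09 (SE 0.30) and Srebf1 by 1.87 (SE 0.31). Myc, Ccnd1, Ccna2, Cdk1, Mki67, Mcm5, Pcna, Rrm2, Foxm1, Igfbp1, Alb, Afp, Hgf and Cyp2e1 did not pass, with log2 changes from -0.28 (Alb) to 1.15 (Igfbp1) for those above background, which Cdk1 and Mki67 were not at 12 h.

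Cholesterol synthesis had 11 of 19 genes down at 12 h and 15 over the list alone, with a median of -1.10 [-1.09, -1.04] (adjusted p = 5.54e-11, or 0.00541 estimated). Hmgcs1, a synthase of the pathway, fell by 2.09 (SE 0.26), and Sc5d, a late enzyme of the pathway, fell by 2.29 (SE 0.21). Fatty acid synthesis had 9 of 17 down and 10 over the list alone (median -0.96 [-1.04, -1.08], adjusted p = 5.97e-07, or 0.0292 estimated). Acly, which makes cytosolic acetyl-CoA, fell by 1.95 (SE 0.34) and Acss2, acetyl-CoA synthetase, fell by 1.84 (SE 0.25). Bile acid genes had 9 of 20 down and 13 over the list alone (median -0.82 [-0.82, -0.90], adjusted p = 4.44e-08, or 0.0712 estimated). Abcb11, the bile salt export pump, fell by 2.06 (SE 0.25). Interferon response genes had 4 of 13 down and 7 over the list alone (median -0.63 [-0.59, -0.80], adjusted p = 2.21e-05, or 0.0285 estimated). Igtp, an interferon-induced GTPase, fell by 1.88 (SE 0.25). Kupffer cell and macrophage markers had 5 of 18 down, 1 up and 12 not past the test (8 down over the list alone), with a median of -0.67 [-0.62, -0.34] (adjusted p = 0.00154, or 0.16 estimated). Clec4f, a lectin of Kupffer cells, fell by 1.44 (SE 0.25), and Csf1r, the receptor that macrophages need for survival, by 1.19 (SE 0.21).

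Other liver function lists lay lower at 12 h with the preset correlation only. Coagulation and complement genes had 5 of 25 down, urea cycle and amino acid genes 5 of 25, cytochrome P450 genes 8 of 31 with 1 up, gluconeogenesis genes 2 of 13 and male-biased genes 3 of 13 (8, 6, 10, 2 and 4 down over the list alone). Their medians lay between -0.30 (gluconeogenesis) and -0.50 (coagulation and male-biased), with adjusted p from 6.28e-06 to 0.0287, and from 0.074 to 0.353 with an estimated correlation. The male-biased median was -0.01 with the block and -0.13 without the 4 arrays, and quantile normalization ended its call (adjusted p = 0.0868). The other medians lay between -0.15 and -0.51 with the block, and between -0.32 and -0.60 without the 4 arrays.

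On the rising side at 12 h, 14 of 23 ribosome biogenesis genes rose and 9 did not pass (16 rose over the list alone). The median was 1.01 [1.0, 1.11] (adjusted p = 1.06e-07, or 0.0312 estimated). The acute-phase list had 12 of 25 up, 1 down and 15 up over the list alone (median 0.93 [0.92, 1.03], adjusted p = 6.21e-08, or 0.0712 estimated). Glucocorticoid and fasting genes had 7 of 17 up and 2 down (median 0.75 [0.85, 0.93], adjusted p = 0.00104, or 0.074 estimated). Genes of ER stress and protein folding had 6 of 22 up (median 0.30 [0.53, 0.59], adjusted p = 0.0296, or 0.356 estimated), led by Xbp1, a transcription factor of the unfolded protein response (1.35, SE 0.21). That call ended without replicate 1 of the 12 h group (adjusted p = 0.437) and without replicate 1 of normal liver (adjusted p = 0.273). Immediate-early genes had 7 of 20 up (median 0.94, adjusted p = 0.000133, or 0.395 estimated), and 0.71 with the block (adjusted p = 0.000791) but 0.36 (adjusted p = 0.0971) without the 4 arrays. The p53 target list had 3 of 13 up (median 0.59, adjusted p = 0.0441, or 0.238 estimated), and 0.34 (adjusted p = 0.092) without the 4 arrays. Cytokine genes had 1 of 10 up (median 0.84 [0.67, 0.54], adjusted p = 0.0179, or 0.395 estimated). Neutrophil markers also had 1 of 9 up (median 0.88 [0.85, 0.90], adjusted p = 0.00585, or 0.224 estimated). Acinar and muscle transcripts had medians of 0.66 and 0.80, with 0 of 32 and 1 of 20 up by limma (3994 of all probe sets had an unadjusted p under 0.05).

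In total 812 rises and 844 falls passed at 12 h (12.2% of probe sets), for 511 and 570 genes, of which 600 and 645 were at least 2-fold. The count of 1656 was 1477 with the block, 1655 without genes of the pancreas and muscle lists, 510 without the 4 arrays and 579 without replicate 2 of normal liver. Of 92 named genes that passed, 87 did so with the block and 49 with only the 4 arrays compared.

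**Figure D3:**
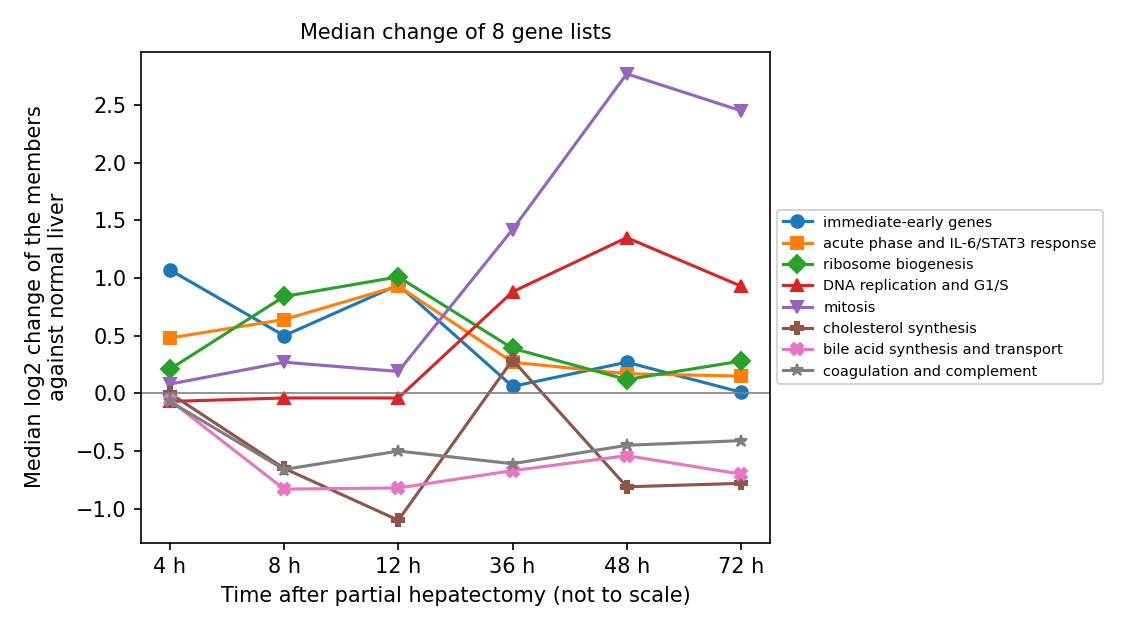
Median log2 change against normal liver (vertical axis) of the members of 8 gene lists at each time after partial hepatectomy (horizontal axis, not to scale), a line per list. The mitosis list climbs from 0.19 at 12 h to 2.77 at 48 h, and the cholesterol synthesis list has its lowest median, -1.10, at 12 h.

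At 36 h Mcm6, a subunit of the replicative helicase, rose by 3.60 (SE 0.41, adjusted p = 0.000465) and Rrm2, which makes deoxyribonucleotides, by 2.63 (SE 0.25, adjusted p = 0.00017). Cdk1, the kinase that starts mitosis, rose by 2.54 (SE 0.23, adjusted p = 0.00014), from a mean intensity of 97.45 ± 27.1 (SD, n = 2) to 839.2 ± 130 (SD, n = 2). Lcn2 rose by 6.28 (SE 0.49, adjusted p = 5.13e-05). Hamp2, a hepcidin gene, fell by 3.91 (SE 0.27, adjusted p = 1.79e-05).

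Ube2c, which tags mitotic proteins for breakdown, was at least 8.83-fold higher at 36 h, Birc5, survivin, at least 8.17-fold and Mki67, the proliferation antigen Ki-67, at least 6.43-fold. Mcm5 (2.54, SE 0.25), Pcna, the sliding clamp of DNA polymerase (1.64, SE 0.21), Ccna2, cyclin A2 (1.52, SE 0.30) and Ccnd1, cyclin D1 (2.15, SE 0.45, adjusted p = 0.0201) also rose. Ly6d, a surface protein of the Ly6 family, and Sult1e1 were at least 44.8-fold and 34.5-fold higher. Apoa4, an apolipoprotein, rose by 4.04 (SE 0.32) and Orm2, an acute-phase protein, by 3.24 (SE 0.35). Saa1 (4.60, SE 0.29), Mt1 (2.50, SE 0.26), Cdkn1a (2.31, SE 0.37) and Dbp (2.38, SE 0.25) passed, as did Socs3 (1.55, SE 0.33), of whose other 2 probe sets 1 went the other way. Falls included Coq8a (-3.50, SE 0.34), Neat1 (-2.65, SE 0.54), Car3, a carbonic anhydrase of male liver and muscle (-2.27, SE 0.22), and Cyp8b1, the enzyme that makes cholic acid (-2.55, SE 0.28). Pigr, which carries immunoglobulins into bile, fell by 2.23 (SE 0.36). Myc, Jun, Foxm1, Igfbp1, Cyp7a1, Cyp2e1, Alb, Afp, Hgf and Srebf1 did not pass, with log2 changes from -1.16 (Myc) to 1.24 (Afp).

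Of 33 mitosis genes 17 rose at 36 h and 16 did not pass (24 rose over the list alone), with a median of 1.42 [1.44, 1.43] (adjusted p = 1.50e-18, or 0.0308 estimated). DNA replication had 11 of 25 up and 13 over the list alone (median 0.88 [1.06, 1.11], adjusted p = 2.46e-12, or 0.0136 estimated). Cholangiocyte and progenitor markers had 3 of 7 up (median 1.24 [0.95, 1.19], adjusted p = 0.000484, or 0.244 estimated), namely Krt8 (1.95, SE 0.40), Krt18 (1.73, SE 0.30) and Cd24a (1.58, SE 0.24). The acute-phase list had 8 of 25 up and 1 down (median 0.27 [0.21, 0.34], adjusted p = 0.00193, or 0.224 estimated, and 0.165 without replicate 1 of normal liver). Ribosome biogenesis had 2 of 23 up (median 0.39 [0.48, 0.41], adjusted p = 0.0123, or 0.201 estimated). Cytokine genes had 2 of 10 up (median 0.43, adjusted p = 0.0343, or 0.453 estimated), and the call ended with the block (0.37, adjusted p = 0.127) and without the 4 arrays (0.14, adjusted p = 0.0971). Neutrophil markers had 1 of 9 up (median 0.50, adjusted p = 0.0417, or 0.348 estimated), and their call ended as well with the block (0.43, adjusted p = 0.082) and without the 4 arrays (0.32, adjusted p = 0.185). The p53 list had 2 of 13 up (median 0.23, adjusted p = 0.0417, or 0.234 estimated), and adjusted p = 0.0538 with the block and 0.0549 under quantile normalization.

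Liver function lists lay lower at 36 h. Fatty acid synthesis had 5 of 17 genes down (8 over the list alone), male-biased genes 3 of 13 (6), gluconeogenesis 2 of 13 (3) and the interferon list 3 of 13 (5). Their medians were -0.77 [-0.74, -0.70], -1.08 [-0.61, -0.59], -0.44 [-0.46, -0.40] and -0.62 [-0.76, -0.56], with adjusted p from 5.80e-09 to 0.000408, and from 0.0191 to 0.0423 with an estimated correlation. Coagulation and complement had 6 of 25 down (16 over the list alone), urea cycle and amino acid genes 6 of 25 (14), cytochrome P450 genes 10 of 31 (14) and bile acid genes 6 of 20 (8). Their medians were -0.61 [-0.65, -0.59], -0.74 [-0.64, -0.68], -0.53 [-0.56, -0.44] and -0.67 [-0.50, -0.61], with adjusted p from 1.78e-13 to 9.83e-06, but from 0.103 to 0.122 with an estimated correlation. Sardh, sarcosine dehydrogenase, fell by 1.99 (SE 0.28), Otc, a urea cycle enzyme, fell by 1.35 (SE 0.23), Cyp2c70 fell by 1.80 (SE 0.25) and Cyp2b9, another cytochrome, fell by 2.20 (SE 0.30). The pancreas and adipose list had 0 of 9 up by limma (2490 of all probe sets had an unadjusted p under 0.05) and a median of 2.03 (adjusted p = 0.00311, or 0.395 estimated). That value rested on replicate 2, whose acinar median was 1148 against 61.59 in replicate 1, and was -0.13 without it. With the block it was 1.47 (adjusted p = 0.0165), and without the 4 arrays -0.13 (adjusted p = 0.416).

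At 36 h 310 rises and 256 falls passed (4.17% of probe sets), for 204 and 187 genes, of which 284 and 219 were at least 2-fold. The total of 566 was 507 with the block, 566 without genes of the pancreas and muscle lists and 81 without the 4 arrays. It was 157 without replicate 2 of normal liver, and 339 and 124 without replicate 1 or 2 of the 36 h group. Of 71 named genes that passed, 66 did so with the block and 31 without the 4 arrays.

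At 48 h genes of mitosis were high. Ube2c was at least 48.1-fold higher (adjusted p = 1.67e-06), Cdca3, a cell division gene, at least 34.9-fold (adjusted p = 1.15e-05) and Birc5 at least 27.7-fold (adjusted p = 3.93e-07). Cdk1 rose by 4.10 (SE 0.23, adjusted p = 1.67e-06), to a mean intensity of 2581 ± 389 (SD, n = 2). Gadd45g, a growth arrest gene, fell by 2.93 (SE 0.41, adjusted p = 0.00194), and Hamp2 by 2.90 (SE 0.27, adjusted p = 8.45e-05).

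Mki67 was at least 19.7-fold higher at 48 h. Cdc20, an activator of the anaphase complex, rose by 4.04 (SE 0.28), Hmmr, a spindle protein, by 3.73 (SE 0.46), Ccna2 by 3.02 (SE 0.30) and Rrm2 by 3.43 (SE 0.25). Mcm5 (2.49, SE 0.25), Pcna (1.55, SE 0.21), Mt1 (1.79, SE 0.26) and the acute-phase genes Saa2 (5.17, SE 0.32), Saa1 (4.63, SE 0.29) and Lcn2 (4.99, SE 0.49) were also up. Myc, a transcription factor of growth, fell by 2.29 (SE 0.39, adjusted p = 0.00817), and Igfbp1, a binding protein of insulin-like growth factors, by 2.02 (SE 0.48, adjusted p = 0.0497, and not past the test under quantile normalization). Thrsp, a lipogenic gene (-2.10, SE 0.40), Coq8a (-2.21, SE 0.34), Hsd3b5 (-2.25, SE 0.42) and Neat1 (-2.49, SE 0.54) fell. Ccnd1 did not pass, at 1.65 (SE 0.45, adjusted p = 0.0939), although 1 of its other 2 probe sets rose. Jun, Socs3, Cdkn1a, Foxm1, Cyp7a1, Cyp2e1, Alb, Afp, Hgf, Srebf1 and Dbp did not pass, with log2 changes from -0.76 (Srebf1) to 1.41 (Cdkn1a).

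**Figure D4:**
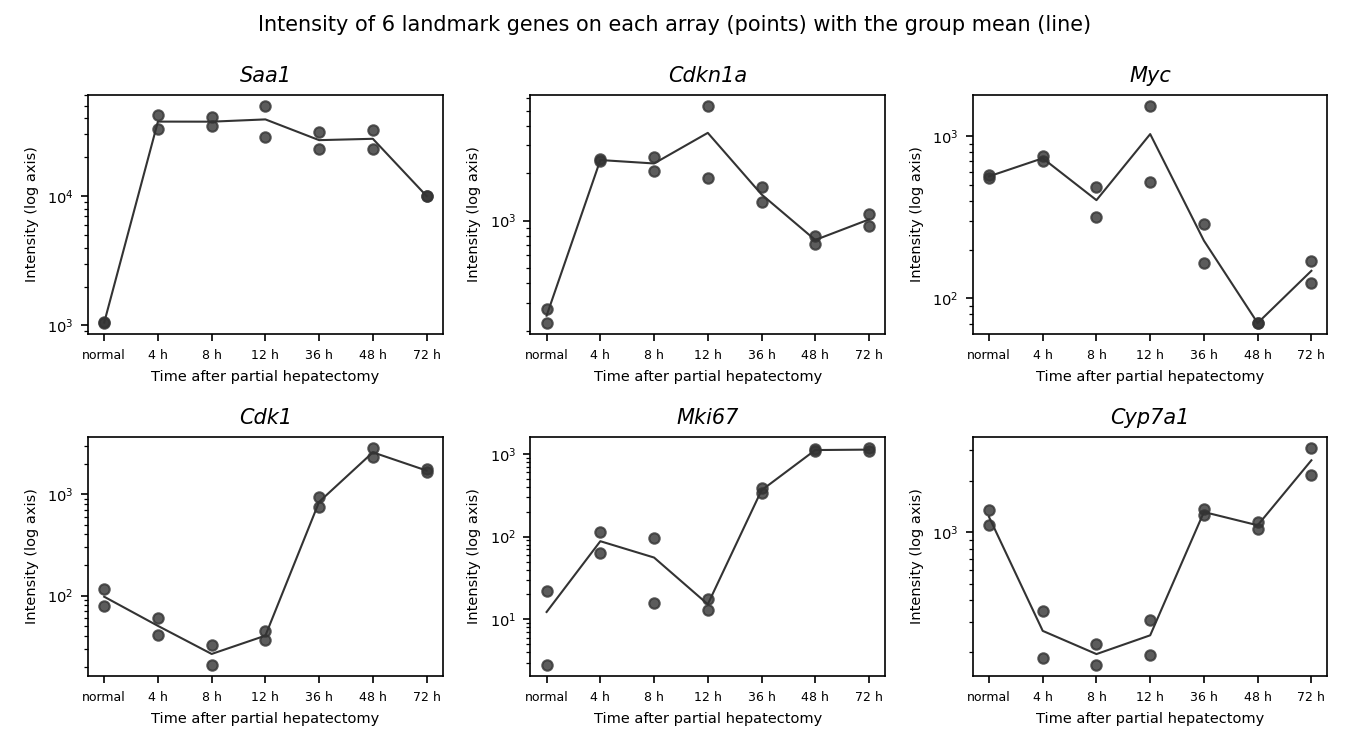
Intensity on a log axis (vertical) of 6 landmark genes on each array (points) by group (horizontal axis), with a line through the group means. The means of Saa1 and Cdkn1a are above normal liver at every time, Cdk1 has its highest mean, 2581, at 48 h, and Cyp7a1 its lowest, 193.6, at 8 h.

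Of 33 mitosis genes 28 rose at 48 h and 5 did not pass (32 rose over the list alone), with a median of 2.77 (adjusted p = 5.92e-52, or 0.00541 estimated). DNA replication had 12 of 25 up and 13 not past the test (23 up and 1 down over the list alone), with a median of 1.35 (adjusted p = 4.53e-19, or 0.00541 estimated). With no array of low 5′ signal at 48 h, neither the block nor the fit without the 4 arrays can move a list median. The acute-phase list had 4 of 25 up and 1 down (median 0.17, adjusted p = 0.0123, or 0.317 estimated). The p53 list had 2 of 13 up (median 0.51, adjusted p = 0.0131, or 0.18 estimated) and the neutrophil markers 0 of 9 by limma (1916 of all probe sets had an unadjusted p under 0.05; median 0.59, adjusted p = 0.0464, or 0.356 estimated). Cholesterol synthesis had 4 of 19 down and 16 over the list alone (median -0.81, adjusted p = 4.37e-15, or 0.00414 estimated). Fatty acid synthesis had 3 of 17 down and 8 over the list alone (median -0.69, adjusted p = 4.88e-09, or 0.0191 estimated). The interferon list had 0 of 13 down over all probe sets and 4 over the list alone (median -0.65, adjusted p = 2.22e-06, or 0.0194 estimated), and gluconeogenesis 0 of 13 and 1 (median -0.43, adjusted p = 0.000249, or 0.033 estimated).

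Further lists lay lower at 48 h with the preset correlation only. They were coagulation and complement (median -0.45, 1 of 25 down), bile acids (-0.54, 2 of 20), urea cycle and amino acids (-0.40, 2 of 25), cytochrome P450 (-0.29, 2 of 31), male-biased genes (-0.43, 2 of 13), fatty acid oxidation (-0.19, 1 of 21) and proteasome subunits (-0.09, 0 of 31). Over the list alone 1, 7, 5, 8, 5, 1 and 0 were down. The adjusted p went from 4.13e-09 to 0.0344, and from 0.0633 to 0.572 with an estimated correlation. Acaa1b, a thiolase of fatty acid oxidation, fell by 1.31 (SE 0.30). Quantile normalization ended the calls of the proteasome (adjusted p = 0.881), fatty acid oxidation (adjusted p = 0.544), cytochrome P450 (adjusted p = 0.253) and neutrophil lists (adjusted p = 0.095).

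In the counts for 48 h, 222 rises and 93 falls passed (2.32% of probe sets), for 146 and 64 genes, of which 218 and 84 were at least 2-fold. The total of 315 was 332 with the block, 315 without genes of the pancreas and muscle lists, 178 without the 4 arrays, 114 without replicate 2 of normal liver and 134 without replicate 1 of the 48 h group. Of 45 named genes that passed, 43 did so with the block and 22 with only the 4 arrays compared.

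At 72 h the mitotic genes were still high. Ube2c was at least 31-fold higher (adjusted p = 4.59e-06) and Cdca3 at least 39.5-fold (adjusted p = 9.94e-06). Hsd3b5 fell by 5.07 (SE 0.42, adjusted p = 3.27e-05) and Gadd45g fell by 4.23 (SE 0.41, adjusted p = 0.000117). Prtn3, a serine protease of neutrophil granules, was at least 15.1-fold higher (adjusted p = 2.21e-05).

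Ccnb2, cyclin B2, rose at 72 h (adjusted p = 4.59e-06), Cdk1 by 3.52 (SE 0.23), Cdc20 by 3.71 (SE 0.28) and Ccna2 by 2.59 (SE 0.30). Mki67 was at least 19.9-fold and Birc5 at least 18.8-fold higher. Rrm2 (2.67, SE 0.25), Mcm5 (1.87, SE 0.25), Pcna (1.14, SE 0.21) and Ccnd1 (2.02, SE 0.45) rose, as did Saa1 (3.18, SE 0.29), Saa2 (3.90, SE 0.32) and Lcn2 (3.90, SE 0.49). Dbp rose by 1.55 (SE 0.25), and Mt1 by 1.83 (SE 0.26), while its other probe set went the other way. Cdkn1a rose by 1.81 (SE 0.37, adjusted p = 0.0234), but not past the test with the block. Neat1 was at least 20.2-fold lower. Dusp1, a MAP kinase phosphatase, fell by 3.09 (SE 0.51), Slc25a25, a mitochondrial carrier, fell by 2.55 (SE 0.27), and Hamp2 (-2.49, SE 0.27), G6pc (-2.34, SE 0.45) and Cyp8b1 (-2.43, SE 0.28) fell too. Myc, Jun, Socs3, Foxm1, Igfbp1, Cyp7a1, Cyp2e1, Alb, Afp, Hgf and Srebf1 did not pass, with log2 changes from -1.72 (Igfbp1) to 1.05 (Cyp7a1).

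Of 33 mitosis genes 27 rose at 72 h and 6 did not pass (29 rose over the list alone), with a median of 2.45 [2.36, 2.49] (adjusted p = 3.19e-43, or 0.0076 estimated). DNA replication had 8 of 25 up, 1 down and 13 up over the list alone (median 0.93 [0.99, 0.96], adjusted p = 1.05e-09, or 0.0194 estimated). The NRF2 list had 2 of 14 up (median 0.57 [0.60, 0.65], adjusted p = 0.0312, or 0.338 estimated), with Gstm3, a glutathione transferase, at 2.35 (SE 0.23). The p53 list had 3 of 13 up (median 0.50, 0.46 with the block; adjusted p = 0.0194, or 0.191 estimated), and adjusted p = 0.0505 without the 4 arrays. Cholangiocyte markers had 1 of 7 up (median 0.71, 0.87 without the 4 arrays; adjusted p = 0.0296, or 0.437 estimated), and lost the call with the block (0.46, adjusted p = 0.0983). Acinar and muscle transcripts had medians of 0.28 and 0.08.

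Male-biased liver genes had 5 of 13 down at 72 h and 9 over the list alone, with a median of -1.49 [-1.25, -1.24] (adjusted p = 8.45e-10, or 0.0137 estimated). Slco1a1, an organic anion carrier, fell by 2.16 (SE 0.31), and Serpina12, vaspin, by 1.91 (SE 0.32). Cholesterol synthesis had 5 of 19 down and 10 over the list alone (median -0.78 [-0.72, -0.79], adjusted p = 1.78e-13, or 0.00458 estimated). Gluconeogenesis had 2 of 13 down (median -0.51 [-0.30, -0.51], adjusted p = 0.000109, or 0.0294 estimated), and the interferon list 0 of 13 over all probe sets by limma and 4 over the list alone (median -0.35 [-0.45, -0.51], adjusted p = 3.90e-05, or 0.0292 estimated; 2061 of all probe sets had an unadjusted p under 0.05).

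Bile acid genes (median -0.70, 4 of 20 down at 72 h), fatty acid synthesis (-0.30, 1 of 17), coagulation (-0.41, 1 of 25), cytochrome P450 (-0.39, 3 of 31), urea cycle (-0.46, 0 of 25) and fatty acid oxidation genes (-0.31, 0 of 21) lay lower with the preset correlation only. Over the list alone 9, 4, 7, 9, 5 and 0 were down. The adjusted p went from 1.96e-08 to 0.00585, and from 0.0793 to 0.189 with an estimated correlation. The medians lay between -0.30 and -0.56 with the block, and between -0.17 and -0.66 without the 4 arrays. Quantile normalization ended the call of fatty acid oxidation (adjusted p = 0.231). The glucocorticoid and fasting list had 2 of 17 up, and 6 down over the list alone (median -0.32 [-0.42, -0.61], adjusted p = 0.0324, or 0.191 estimated, and adjusted p = 0.0544 under quantile normalization). Growth factors and receptors had 1 of 20 down, the growth hormone receptor Ghr (-1.26, SE 0.24), with a median of -0.04 [-0.32, -0.46] (adjusted p = 0.0343, or 0.143 estimated). Endothelial markers had 0 of 17 down (median -0.19 [-0.18, -0.11], adjusted p = 0.0348, or 0.15 estimated). Beside these counts of 0, 2061 of all probe sets had an unadjusted p under 0.05 in limma.

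By limma 220 rises and 118 falls passed at 72 h (2.49% of probe sets), for 143 and 73 genes, of which 215 and 110 were at least 2-fold. The total of 338 was 286 with the block, 338 without genes of the pancreas and muscle lists and 63 without the 4 arrays. It was 514 and 123 without replicate 1 or 2 of normal liver, and 156 and 108 without replicate 1 or 2 of the 72 h group. Of 48 named genes that passed, 44 did so with the block and 26 without the 4 arrays.

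Early times (4, 8 and 12 h, 6 arrays) were compared with late times (36, 48 and 72 h, 6 arrays), not with normal liver. Gadd45b (adjusted p = 5.65e-05, not above background at 48 and 72 h), Pim3, a growth-promoting kinase (3.09, SE 0.28, adjusted p = 1.49e-05), Igfbp1 (2.69, SE 0.28, adjusted p = 4.25e-05) and Il1r1 (2.68, SE 0.14, adjusted p = 1.82e-07) were higher early. Cdk1 was at least 16-fold lower early (adjusted p = 5.09e-09), Ube2c at least 13.8-fold (adjusted p = 5.84e-08) and Birc5 at least 9.47-fold (adjusted p = 5.09e-09). Cyp7a1 was lower early, at -2.49 (SE 0.17, adjusted p = 2.72e-06).

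Lpin1 (2.50, SE 0.17), Pdk4 (3.09, SE 0.33), Gadd45g (3.07, SE 0.24), Cyp2b10, a drug-metabolizing enzyme (2.60, SE 0.17), and Txnip, an inhibitor of glucose uptake (2.44, SE 0.30), were higher early too, as were Myc (1.86, SE 0.23), Socs3 (2.31, SE 0.19), Jun (0.94, SE 0.18), Cdkn1a (1.28, SE 0.22), Mt1 (1.41, SE 0.15) and Saa1 (0.95, SE 0.17). Lower early were Mki67 and Mcm6, neither above background at 12 h (adjusted p = 9.87e-07 and 3.25e-06), Rrm2 (-2.42, SE 0.14), Ccna2 (-2.20, SE 0.17), Mcm5 (-2.14, SE 0.14), Pcna (-1.53, SE 0.12), Ccnd1 (-1.15, SE 0.26), Srebf1 (-1.19, SE 0.18) and Dbp (-0.76, SE 0.14). Cdca3 was lower early as well (-2.92, SE 0.18), while its other probe set went the other way. Cyp2e1, Alb, Hgf, Afp and Foxm1 did not pass, with differences from -0.35 (Foxm1) to 0.31 (Cyp2e1). Of 33 mitosis genes 29 were lower early and 4 did not pass (median -1.97, adjusted p = 3.65e-33, or 0.0136 estimated), and 21 of 25 DNA replication genes (median -1.22, adjusted p = 3.22e-19, or 0.00541 estimated). Immediate-early genes had 12 of 20 higher (median 0.95, adjusted p = 5.72e-10, or 0.204 estimated), glucocorticoid and fasting genes 10 of 17 with 2 lower (median 0.97, adjusted p = 4.62e-07, or 0.0234 estimated) and ribosome biogenesis 12 of 23 (median 0.48, adjusted p = 1.09e-06, or 0.0423 estimated). The acute-phase list had 10 of 25 higher (median 0.45, adjusted p = 2.51e-09, or 0.0524 estimated) and cytokines 3 of 10 (median 0.63, adjusted p = 0.000133, or 0.217 estimated). ER stress genes had 4 of 22 higher (median 0.23, adjusted p = 0.00258, or 0.224 estimated) and urea cycle genes 5 of 25 with 2 lower (median 0.30, adjusted p = 0.00166, or 0.384 estimated). The block cannot move these medians, since early and late times hold 2 arrays of low 5′ signal each.

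Other differences between the phases were those of coagulation genes (3 of 25 higher, median 0.10, adjusted p = 0.0347, or 0.564 estimated), male-biased genes (4 of 13 higher and 1 lower, median 0.32, adjusted p = 0.0172, or 0.177 estimated) and neutrophil markers (2 of 9 higher, median 0.25, adjusted p = 0.026, or 0.317 estimated). Without the 4 arrays the calls of the coagulation (0.05, adjusted p = 0.406) and male-biased lists (0.27, adjusted p = 0.0761) ended, and under quantile normalization those of the urea cycle (adjusted p = 0.356), coagulation (adjusted p = 0.853) and male-biased lists (adjusted p = 0.143). The pancreas and adipose markers were higher early in 8 of 9 cases (median 3.23, 3.59 without the 4 arrays; adjusted p = 7.82e-08, or 0.177 estimated), with 27 of 32 acinar and 15 of 20 muscle transcripts. Clps was at 3.33 (SE 0.27).

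The contrast called 809 probe sets higher early and 1347 lower (15.9%), for 511 and 856 genes. The total of 2156 was 2417 with the block, 2094 without genes of the pancreas and muscle lists and 817 without the 4 arrays. Within those 4 arrays, where 8 and 12 h were set against 36 and 72 h, 2 arrays against 2, limma called 0, with 2363 at an unadjusted p under 0.05, and the differences correlated at 0.71 with those of the other 10 arrays across probe sets, which are not independent replicates. All 82 named genes that passed did so with the block, and 61 without the 4 arrays.

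Between 4 and 12 h Hsd3b5 was at least 15.8-fold lower at 12 h than at 4 h (adjusted p = 0.000706), and Keg1 fell by 3.57 (SE 0.24, adjusted p = 6.06e-05). Sult1e1 was at least 10.5-fold higher (adjusted p = 0.00296), and Cidec rose by 2.93 (SE 0.36, adjusted p = 0.00246). Mb fell (adjusted p = 0.00246), and Clps fell by 2.99 (SE 0.46, adjusted p = 0.0082).

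Neat1 rose (adjusted p = 0.0165) from 4 to 12 h, Apoa4 by 2.10 (SE 0.32) and Odc1, the first enzyme of polyamine synthesis, by 1.72 (SE 0.25). Hal (-2.89, SE 0.31), Coq8a (-2.62, SE 0.34), Nr0b2 (-2.49, SE 0.34) and Acly (-2.13, SE 0.34) fell. None of the 22 landmark genes tested passed by limma, with 2346 of all probe sets at an unadjusted p under 0.05; those above background lay between -0.84 (Igfbp1) and 0.45 (Hgf). Cholesterol synthesis had 8 of 19 genes down and 12 over the list alone, with a median of -1.09 [-1.0, -0.90] (adjusted p = 1.95e-15, or 0.00414 estimated). Fatty acid synthesis had 5 of 17 down (median -0.77 [-0.78, -0.86], adjusted p = 9.95e-10, or 0.0161 estimated). Kupffer cell and macrophage markers had 5 of 18 down and 11 over the list alone (median -0.85 [-0.83, -0.61], adjusted p = 1.99e-09, or 0.0292 estimated), among them Lyz2, lysozyme (-1.34, SE 0.22). Ribosome biogenesis had 5 of 23 up and 12 over the list alone (median 0.79 [0.86, 0.89], adjusted p = 2.48e-08, or 0.0292 estimated). Interferon genes had 2 of 13 down (median -0.57 [-0.56, -0.71], adjusted p = 8.24e-06, or 0.0234 estimated). Gluconeogenesis had 1 of 13 down (median -0.49, -0.37 with the block; adjusted p = 0.000985, or 0.0482 estimated), and -0.26 (adjusted p = 0.0693) without the 4 arrays. Bile acid genes had 5 of 20 down (median -0.55 [-0.58, -0.72], adjusted p = 7.29e-09, or 0.0593 estimated).

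ER stress genes had 2 of 22 up from 4 to 12 h (5 over the list alone, median 0.41 [0.66, 0.59]; adjusted p = 0.00207, or 0.222 estimated, and 0.21 without replicate 1 of the 12 h group). Coagulation (0 of 25 down by limma), urea cycle (2 of 25), cytochrome P450 (1 of 31) and male-biased genes (2 of 13) had medians of -0.42 [-0.47, -0.59], -0.28 [-0.19, -0.18], -0.29 [-0.31, -0.49] and -0.30 [-0.33, -0.37], with 5, 3, 1 and 2 down over the list alone. Their adjusted p went from 4.40e-08 to 0.00154, and from 0.0855 to 0.317 with an estimated correlation. The pancreas and adipose markers had 2 of 9 down and 8 over the list alone (median -3.58 [-3.83, -2.95], adjusted p = 1.24e-07, or 0.18 estimated), and muscle transcripts 10 of 20. Immediate-early genes (median -0.22, adjusted p = 0.109) and cytokines (-0.46, adjusted p = 0.0578) did not pass, but did with the block (-0.43 and -0.56, adjusted p = 0.0086 and 0.00466) and without the 4 arrays (-0.77 and -0.56, adjusted p = 1.23e-09 and 0.000946). From 4 to 12 h 117 probe sets rose and 205 fell. The total of 322 was 279 with the block, 306 without genes of the pancreas and muscle lists and 144 without the 4 arrays. It was 36 and 43 without replicate 1 or 2 of the 4 h group, 195 without either replicate of the 8 h group and 591 without replicate 2 of the 12 h group. Of 50 named genes that passed, 46 did so with the block and 17 without replicate 1 of the 4 h group.

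Between 36 and 72 h Ccnb2 rose by 2.39 (SE 0.26, adjusted p = 0.00349) and Cdc20 by 2.20 (SE 0.28, adjusted p = 0.00542). Sult1e1 fell by 3.72 (SE 0.48, adjusted p = 0.00542), Msmo1, a sterol demethylase, fell by 2.68 (SE 0.32, adjusted p = 0.00356) and Hsd3b5 fell by 2.84 (SE 0.42, adjusted p = 0.011). Prtn3 rose by 2.71 (SE 0.29, adjusted p = 0.00285).

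Coq8a rose by 2.06 (SE 0.34) from 36 to 72 h, Ptgr1, a reductase of prostaglandins, by 2.24 (SE 0.22) and Stmn1, a microtubule regulator, by 1.84 (SE 0.24). Idi1 (-2.19, SE 0.29) and Cyp51 (-1.97, SE 0.23), both of cholesterol synthesis, fell, as did Fgf21, a fasting hormone of the liver (-2.10, SE 0.35), Cidec (-2.40, SE 0.36) and Ccl2, a monocyte-attracting chemokine (-1.52, SE 0.27). None of the 22 landmark genes passed by limma, with 943 of all probe sets at an unadjusted p under 0.05; they lay between -1.51 (Igfbp1) and 1.49 (Mki67). Of 33 mitosis genes 10 rose and 23 did not pass (23 rose over the list alone), with a median of 1.11 [1.11, 1.07] (adjusted p = 2.31e-31, or 0.0137 estimated). Cholesterol synthesis had 8 of 19 down, and 13 down and 1 up over the list alone (median -1.0 [-1.0, -1.08], adjusted p = 2.56e-20, or 0.00414 estimated). The glucocorticoid and fasting list had 1 of 17 down and 12 over the list alone (median -1.0 [-1.0, -1.01], adjusted p = 4.13e-10, or 0.0136 estimated). Cholangiocyte markers had 1 of 7 down, Cd24a (-1.52, SE 0.24), and a median of -0.45 (-0.55 without the 4 arrays; adjusted p = 0.0193, or 0.399 estimated).

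Lists of which at most 1 member passed over all probe sets also differed between 36 and 72 h, with the preset correlation only. Lower at 72 h were the lists for the acute phase (median -0.15), cytokines (-0.21), DNA replication (-0.19), ribosome biogenesis (-0.17), the proteasome (-0.23), ER stress (-0.21), heat shock (-0.11), male-biased genes (-0.13) and the circadian clock (-0.38). Their adjusted p went from 0.000133 to 0.0487, and from 0.117 to 0.395 with an estimated correlation. The call of ER stress ended under quantile normalization (adjusted p = 0.112) and without replicate 1 of the 36 h group (adjusted p = 0.445), among other settings. The pancreas and adipose list was at -1.89 (adjusted p = 0.000294, or 0.317 estimated), and at 0.36 without replicate 2 of the 36 h group and 0.41 without the 4 arrays. Higher at 72 h were fatty acid synthesis (0.36), cytochrome P450 (0.21), urea cycle (0.39) and coagulation genes (0.28) and lymphocyte markers (0.44), with adjusted p from 5.26e-05 to 0.0134, and from 0.0524 to 0.395 with an estimated correlation. The block cannot move a median here, since each of these times holds 1 array of low 5′ signal. Without the 4 arrays the medians of cytokines (-0.04), DNA replication (-0.42), heat shock (-0.17) and male-biased genes (-0.25) moved, and the cytochrome P450 (0.07, adjusted p = 0.416), urea cycle (0.30, adjusted p = 0.25) and coagulation lists (0.18, adjusted p = 0.0613) lost the call. Erythroid markers passed camera in none of the comparisons, with 0.27 here (adjusted p = 0.142). Over the 288 list tests, the median, mean and tested direction differed in sign in 32, none of which passed.

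From 36 to 72 h 38 probe sets rose and 38 fell, with 91 in total with the block and 76 without genes of the pancreas and muscle lists. Without the 4 arrays 1 passed, Sult1e1. The total of 76 was 10 without replicate 2 of the 36 h group, and 13 and 16 without replicate 1 or 2 of the 72 h group. All 29 named genes that passed did so with the block, and 1 without the 4 arrays.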

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

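The tests of the link between acinar and muscle transcripts, of dilution, of the processing group and of the clock genes were chosen only after the results were seen. The islet test was written after the rise of acinar transcripts was seen and before any islet value was. The test of other splits of the arrays was written before its result, and that of splits of whole times after it.

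In limma early and late times differed in 2156 probe sets, 12 and 4 h in 322, and 72 and 36 h in 76. Of 100 splits of the 12 arrays after hepatectomy into 6 and 6, drawn from 462, 1 gave as many probe sets as the real split with 1690 in a fit of 2 groups, namely the real one, and the highest of the others gave 1. Those splits part the 2 arrays of a time, which the real one does not. Splits that keep the times whole number 10, too few for a share under 0.05; the real one gave 1690 and the highest other 46.

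Between early and late times 13 lists differed by camera, and 4 of them with an estimated correlation. The median differences were 0.95 for immediate-early genes, 0.45 for the acute phase, 0.63 for cytokines and NF-kB targets, 0.97 for the glucocorticoid and fasting response, -1.22 for DNA replication, -1.97 for mitosis and 0.48 for ribosome biogenesis. They were 0.23 for ER stress, 0.30 for the urea cycle, 0.10 for coagulation, 0.32 for male-biased genes, 0.25 for neutrophil markers and 3.23 for pancreas and adipose markers.

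From 4 to 12 h 13 lists differed, and 6 of them with an estimated correlation. The differences were -0.57 for interferon response, 0.79 for ribosome biogenesis, 0.41 for ER stress, -1.09 for cholesterol synthesis, -0.77 for fatty acid synthesis, -0.55 for bile acids and -0.29 for cytochrome P450. They were -0.49 for gluconeogenesis, -0.28 for the urea cycle, -0.42 for coagulation, -0.30 for male-biased genes, -0.85 for Kupffer cell and macrophage markers and -3.58 for pancreas and adipose markers.

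From 36 to 72 h 19 lists differed, and 3 of them with an estimated correlation. The differences were -0.15 for the acute phase, -0.21 for cytokines, -1.0 for the glucocorticoid and fasting response, -0.19 for DNA replication, 1.11 for mitosis, -0.17 for ribosome biogenesis, -0.23 for the proteasome, -0.21 for ER stress, -0.11 for heat shock and -1.0 for cholesterol synthesis. They were 0.36 for fatty acid synthesis, 0.21 for cytochrome P450, 0.39 for the urea cycle, 0.28 for coagulation, -0.13 for male-biased genes, -0.38 for the circadian clock, 0.44 for lymphocyte markers, -0.45 for cholangiocyte markers and -1.89 for pancreas and adipose markers (0.36 without PHx 36 h replicate 2).

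Of 32 pancreatic acinar transcripts 11 rose at 4 h and 29 at 8 h, and of 20 muscle transcripts 16 and 13; the pancreas and adipose list lost its call with an estimated correlation (adjusted p = 0.107 and 0.109). Of the acinar transcripts, on a list drawn up after the top genes were seen, 14 lay above background in both arrays of normal liver and 8 are on a list fixed before; the brightest at 8 h, Ctrb1, went from 137 ± 12.9 (SD, n = 2) to 35260 ± 4200 (SD, n = 2). A candidate explanation is pancreas tissue or RNA carried over with the liver. Islet transcripts above background at 8 h had a median of 1.63 then, over the bound of 1 set before. Leaving out dim ones favours a rise. Carry-over stays open, as only 2 of 15 islet transcripts were bright enough to test. They were Ins2 (at least 11.1-fold higher, adjusted p = 0.00219) and Pyy (0.59, SE 0.36, adjusted p = 0.333). The need for more members was added after their number was seen. A response of liver cells shared by both kinds of gene stays open too, as no value here decides it: the acinar and muscle medians went together over the 12 arrays after hepatectomy (Spearman rho 0.81, permutation p = 0.0024; Pearson r 0.74, permutation p = 0.0061, and 0.81 without the 2 farthest arrays), but the lists were drawn up from genes seen high at these times and the arrays of a time are not independent, so this decides nothing; the 8 h arrays form a cluster apart, the medians moved in opposite directions from 4 to 8 h, a condition added after seeing them, and without Car3 and Eno3, taken off the muscle list after the first result, rho was 0.80.

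Several liver function lists lay lower at 8 and 12 h (with an estimated correlation only cholesterol synthesis, and at 12 h fatty acid synthesis), and most calls fell at these times. Against dilution of liver RNA by another tissue as the cause at 12 h, the 56 members of the bile acid, cholesterol and fatty acid synthesis lists had a median of -0.97 at 12 h beside -0.74 at 8 h, while the acinar median went from 6.04 to 0.66. At 8 h the fatty acid oxidation list had a median of -0.12. Against the processing group as the whole cause of the many calls, the smaller of the 8 and 12 h counts was 1198 with that group as a block, beside 394 as the larger of 4 and 48 h; without its 4 arrays, with 1 array left at 8 h, that time had 364 beside 317 at 4 h, but leaving out only replicate 1 of 8 h, not of that group, also gave 534. A response of the liver to the operation stays open, as do other differences between the arrays, since nothing separates the time from its single pair of arrays.

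Circadian clock genes differed between times. Against the hour of collection as the whole cause, with all operations at one hour, 6 of 14 members differed between 36 and 12 h, a day apart, when adjusted over the list alone. Dbp was higher at 36 h by 1.40 (SE 0.25), Usp2 by 1.70 (SE 0.53) and Wee1 by 1.18 (SE 0.32), and Per1 fell by 1.40 (SE 0.51), Bhlhe40 by 1.24 (SE 0.45) and Nr1d1 by 1.14 (SE 0.39). The count was 6 with the processing group as a block, and between 72 and 48 h limma called 0 (1 had an unadjusted p under 0.05, and the smallest adjusted p was 0.0639). The hour of each operation is not given in the sources used here, so unequal hours stay open beside an effect of the operation on the clock.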

How the results depend on the processing

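The settings with the processing group, without its 4 arrays and within them were chosen only after the data were seen. The 2 arrays per group limit the precision, and a group left with 1 array is assumed to vary like the others. Genes near the background could not be followed below it, so folds against a side not above it are lower bounds. Of the values of named genes that passed in the main fit or in the alternative, 0 changed sign in any setting. Values that passed in neither were not checked for a change of sign. The causes of the shifts below were not tested, except where fewer arrays or no test explain them.

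With a pseudocount 4 times larger the 12 against 4 h count was 507. Array weights gave 584 at 12 h, 168 at 48 h, 190 for 12 against 4 h and 180 for 72 against 36 h. The 2-fold criterion with no test gave 810 at 4 h, 954 at 36 h, 677 at 48 h and 734 at 72 h. With only the 4 arrays compared, limma called 323 at 12 h, 160 at 36 h, 92 at 48 h and 180 at 72 h.

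With an estimated correlation the called lists went from 13 to 2 at 4 h, 16 to 2 at 8 h, 18 to 4 at 12 h, 17 to 6 at 36 h, 16 to 6 at 48 h and 18 to 6 at 72 h, and from 13 to 4 for early against late, 13 to 6 for 12 against 4 h and 19 to 3 for 72 against 36 h. Of 143 called list results 39 held with it, and 38 held in every setting run for lists. It gave the highest p of all settings for 121 of the 143, and another setting did for 22 (at most 0.968).

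Without the 4 arrays of low 5′ signal the counts were 364 at 8 h, 510 at 12 h, 81 at 36 h, 178 at 48 h, 63 at 72 h, 817 for early against late, 144 for 12 against 4 h, 1 for 72 against 36 h and 523 for any time. Within those 4 arrays 8 and 12 h against 36 and 72 h gave 0 in limma (2363 at an unadjusted p under 0.05). The median of the pancreas and adipose list reversed without them and without PHx 36 h replicate 2, to -0.13 in both cases at 36 h, and to 0.41 and 0.36 for 72 against 36 h. Without replicate 1 it was 4.91 at 36 h and -4.35 for 72 against 36 h, so replicate 2 carried the signal. At 12 and 48 h the list was not called, but passed without the 4 arrays (adjusted p = 7.51e-05 and 0.00724).

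Leaving out 1 array at a time gave 80 to 554 probe sets at 4 h, 454 to 1717 at 8 h, 579 to 2189 at 12 h, 124 to 842 at 36 h, 114 to 471 at 48 h and 108 to 514 at 72 h. It gave 1483 to 2513 for early against late, 36 to 591 for 12 against 4 h, 10 to 101 for 72 against 36 h and 1187 to 2265 for any time. Called lists ranged from 7 to 14 at 4 h, 16 to 18 at 8 h, 15 to 19 at 12 h, 14 to 21 at 36 h, 13 to 17 at 48 h, 13 to 19 at 72 h, 12 to 14 for early against late, 13 to 14 for 12 against 4 h and 13 to 20 for 72 against 36 h. Of the 143 list calls, 0 ended without PHx 8 h replicate 2 and 23 without normal liver replicate 1.

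With the replicate number as a block the counts were 325, 1382, 1764, 617, 326 and 336 at the 6 times, 2243 for early against late, 314 for 12 against 4 h, 76 for 72 against 36 h and 1787 for any time. With the processing group as a block they were 394, 1198, 1477, 507, 332 and 286, then 2417, 279, 91 and 1739. The labels do not pair the arrays; differences between replicates correlated above 0.1 in 9 of 21 pairs of groups (-0.19 to 0.53), and in 6 of 6 among the groups with an array of low 5′ signal (0.14 to 0.31). The fit without the 4 arrays ended 217 calls of single genes and 11 of lists, and 2 reversed lists lost theirs too; leaving out normal liver replicate 2 ended 154, and comparing only 4 arrays 120. Quantile normalization ended 23 calls of single genes and 12 of lists, and brought 26 genes past the threshold; no filter ended 61 and 8, and the processing group as a block 29 and 4.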

Other observations

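The genes below, outside the gene lists, were grouped after their values were seen, and the groups were not tested. Of these, 2 code for proteins of lipid handling. Cidec, of lipid droplets, had a mean intensity of 33.7 ± 3.82 (SD, n = 2) in normal liver, 2259 ± 190 (SD, n = 2) at 8 h and 68.75 ± 15.3 (SD, n = 2) at 48 h. Apoa4, a lipoprotein component, went from 1340 ± 30.5 (SD, n = 2) to 23010 ± 726 (SD, n = 2) at 36 h.

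Other genes were high or low in a few groups only. Sult1e1, which inactivates oestrogens, had means of 12.7 ± 9.48 (SD, n = 2) in normal liver, 1970 ± 465 (SD, n = 2) at 36 h and 26.4 ± 10.3 (SD, n = 2) at 48 h. Prtn3, a protease of neutrophil granules, was at 16.65 ± 0.495 (SD, n = 2) in normal liver, 17.7 ± 0.707 (SD, n = 2) at 8 h and 849.6 ± 82.1 (SD, n = 2) at 72 h.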
